A study of Bos taurus with 22 samples.

How the data were processed

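Subcutaneous adipose tissue of 11 first-calving Holstein heifers was sampled 30 days before and 14 days after calving and hybridised to 22 Affymetrix bovine arrays. The authors summarised each probe set with MAS5, per the submitters' processing notes. Its version and settings, and the genome build, are not given in the sources used here. The deposited values are linear signal intensities. Their trimmed mean, with 2% of values removed at each end, was 125 on every array, so the authors had scaled each array as a whole. The median bovine signal ran from 39.9 to 47.4. Array data give no read depth, and the number of arrays limits the precision.

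The table held 24128 probe sets, of which 112 were array controls and were left out of the tests, leaving 24016 bovine probe sets. The annotation table gave 1 gene symbol to 13318 probe sets, several to 86 and none to 10724. Probe sets with several symbols or none were tested and counted but not named. Of the symbols, 13283 were taken through the Entrez identifier from a RefSeq gene table of the ARS-UCD2.0 assembly, 2 through an accession, and 33 were kept as annotated. No coordinates were used.

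Values were taken as log2(signal + 7.78), where 7.78 was the median over arrays of the 20th percentile. Fold changes are on that scale, which understates the change of dim genes. Probe sets whose mean reached the 40th percentile were kept, which left 14410. A gene was represented by its kept probe set with the highest mean, and 6984 genes were tested. The test was limma's moderated test (limma 3.58.1 in R 4.3.3) with an intensity trend, cow as a fixed block, and Benjamini-Hochberg adjustment over the kept probe sets at a threshold of 0.05. All adjusted p-values of single genes come from that limma fit unless another test is named.

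The cow number in the titles paired the samples, and the series design describes sampling of the same animals at both times. For the pair labelled cow 387 this is in doubt. That pair was kept in the main fit and in the counts over 11 cows. After subtraction of group means, the correlation between the arrays of a cow lay between 0.18 and 0.43 for 10 cows and was -0.09 for cow 387. The postpartum array of another cow correlated better with the prepartum array of cows 341 (0.31 against 0.23), 330 (0.24 against 0.18), 384 (0.30, with cow 386, against 0.21) and 387 (0.64, with cow 384). The matches of cows 384 and 387 joined arrays with raised skeletal muscle markers. They cannot tell shared muscle RNA from a shared animal. The titles also end in 1 of 2 codes whose meaning is not stated. They divide the cows into array set 1 (5 cows) and array set 2 (6 cows), each with both samples of its cows, and the difference of the postpartum effect between the sets was fitted as an interaction.

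A total of 33 lists (22 gene lists and 11 lists of cell type markers) were tested with camera, limma's competitive gene set test, with a preset correlation of 0.01, where at least 3 genes were kept. Camera was repeated with an estimated correlation. Named genes were chosen by rule: the 8 genes with the largest rise and the 8 with the largest fall among called genes with at least 9 of 11 cows in that direction, the 2 called members of each list with the largest change (3 where a list had at least 8 called members), a fixed set of lipid, insulin and growth hormone genes, and genes that a check was about. One gene of the fixed set is not reported here. The lists, this rule, the tests and most alternatives were fixed before the data were examined.

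The test was tried on simulated data in which each probe set kept its measured cow means and residual spread and 200 of 14410 were changed. For the postpartum effect, 95.0% of 100 probe sets changed by 1 log2 unit and 53.0% of 100 changed by 0.5 were recovered, with 8 false calls among 156. For the difference between array sets, 93.0% changed by 2 log2 units and 43.0% changed by 1 were recovered. Simulated residuals were independent between genes, unlike those of real lists. Alternatives varied the block, normalization, pseudocount, filter, variance model, test, array weights, array set, threshold, left-out cows, probe sets of a gene and list test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.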

Results

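The arrays measured transcripts in subcutaneous adipose tissue of 11 Holstein heifers around their first calving. Each was sampled 30 days prepartum and 14 days postpartum, so that by the labels every cow served as its own control. For the pair labelled cow 387, kept in the tests over 11 cows, this is in doubt. Each group held 11 arrays. Median rank correlations of an array with the other arrays ran from 0.877 (postpartum, cow 384) to 0.954. The 3 prime over 5 prime signal ratio of GAPDH, a sign of RNA quality, differed by 0.03 log2 units postpartum against prepartum (SD 0.28, n = 11 cows, exact sign-flip p = 0.768), and that of actin by -0.41 (SD 1.36, n = 11 cows, exact sign-flip p = 0.329). Single arrays stood apart. The GAPDH ratio was 1.26 in the postpartum array of cow 341, against 0.58 in its prepartum array and at most 0.62 in the others. It was lowest in the postpartum array of cow 384 (-0.10) and the prepartum array labelled cow 387 (-0.05). These 2 arrays also had the lowest actin ratios (-0.07 and -0.12) and the highest skeletal muscle markers. The ratios cannot tell RNA quality from tissue content there.

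Several arrays had high levels of transcripts that are markers of other tissues. The median of 17 skeletal muscle markers, which include fast myosin MYH1, actin ACTA1 and troponin TNNC2, stood 8.03 log2 units above the gene medians in the postpartum array of cow 384 and 7.25 above in the prepartum array labelled cow 387. It stood 3.73 above in the postpartum array of cow 386 and 2.66 above in the prepartum array of cow 384. KRT10, a keratin of the upper epidermis, reached 9.34, 12.55, 9.35 and 11.48 in the prepartum arrays of cows 331, 341, 330 and 382, and the highest postpartum level was 6.90. KRT5, a basal keratin, had 2 kept probe sets: one reached 6.10, 10.94, 5.78 and 9.78 in these arrays and at most 5.75 in the others, and the other stood at 7.32, 7.60, 7.92 and 7.19, within the range of the others (6.48 to 7.92). KRT10 was lower postpartum in 10 of 11 cows (mean log2 change -1.77, SD 2.27, n = 11; exact sign-flip p = 0.00977), but it did not pass the test over all probe sets (adjusted p = 0.102).

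**Figure D1:**
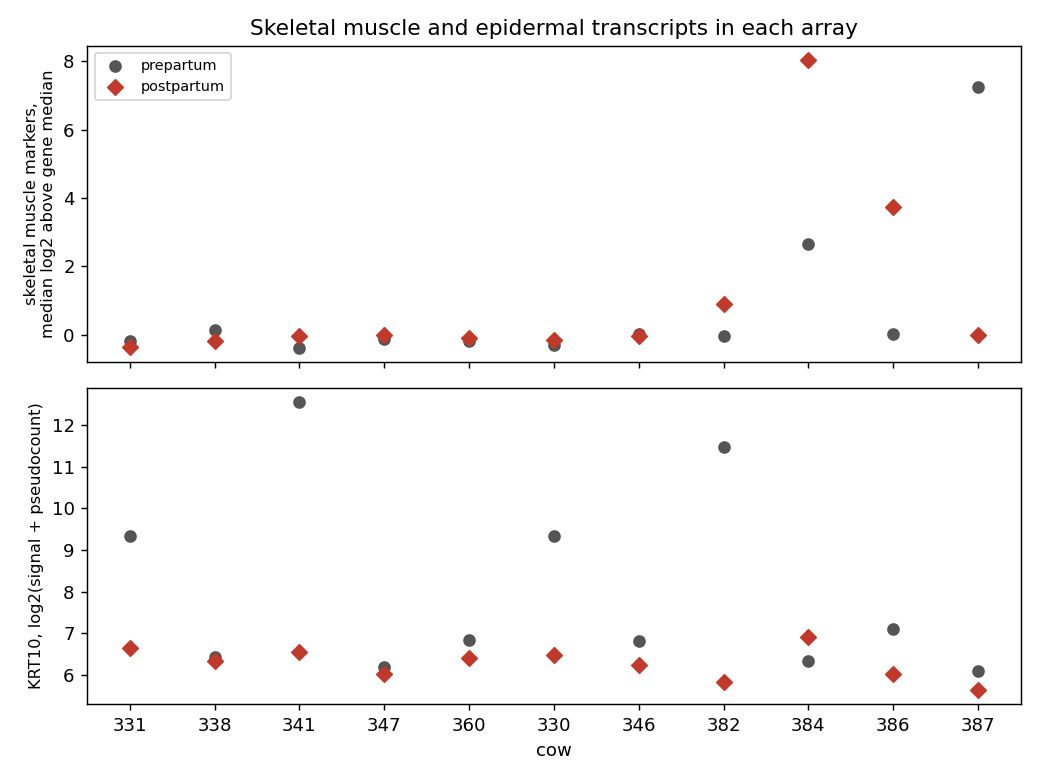
Skeletal muscle markers (upper panel, median log2 level of 17 genes above each gene's median over the arrays) and KRT10 (lower panel, log2 of signal plus pseudocount) in each array, by cow, with grey circles for prepartum and red diamonds for postpartum. Muscle markers reached 8.03 in the postpartum array of cow 384 and 7.25 in the prepartum array labelled cow 387, and KRT10 reached 12.55 in the prepartum array of cow 341.

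The main comparison asked how adipose transcripts differed between late pregnancy and early lactation. Among genes of fat synthesis SCD, which desaturates stearate, fell 3.55-fold (log2 change -1.83, SE 0.32, adjusted p = 0.00774, 11 of 11 cows), and FASN, the fatty acid synthase, fell 3.08-fold (log2 change -1.62, SE 0.36, adjusted p = 0.0239, 9 of 11 cows). LEP, which encodes the hormone leptin, fell 3.44-fold (log2 change -1.78, SE 0.40, adjusted p = 0.0268, 9 of 11 cows). PDK4, a kinase that restrains pyruvate oxidation, rose 1.68-fold (log2 change 0.74, SE 0.16, adjusted p = 0.0205, 10 of 11 cows). FASN, LEP and PDK4 did not pass with an ordinary paired test. In all, 494 of 14410 probe sets passed limma's test, 208 higher and 286 lower postpartum, and 259 of 6984 genes did, 108 higher and 151 lower. Without cows 384 and 387, an alternative chosen after the data were seen, 1070 probe sets passed (522 higher, 548 lower), and 472 of the 494 were among them. Leaving out single cows gave 242 (without cow 382) to 969 (without cow 384).

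The largest fall was that of LOC515676, an unnamed locus, at 7.54-fold (log2 change -2.91, SE 0.30, adjusted p = 0.00085, 11 of 11 cows). CRYM, a thyroid hormone binding protein, fell by 2.01 log2 units and MAOB, a mitochondrial amine oxidase, fell by 1.72, each in 11 of 11 cows. RARRES1 fell by 1.78, CLDN10, a tight junction claudin, fell by 1.75, and TF, the iron carrier transferrin, fell by 1.74. Among genes that rose, PMEL, a melanosome protein, rose by 1.69 log2 units (SE 0.25, adjusted p = 0.00308, 11 of 11 cows), ASGR1 by 1.60, PI16 by 1.44, TTR, the thyroxine carrier transthyretin, by 1.41 and PAMR1 by 1.33. PMEL, ASGR1 and ACKR4 (log2 change 1.12) were dim, with prepartum means of 4.44, 4.86 and 4.65 on the log2 scale, and the order of the rises depended on the pseudocount. TP53INP1 rose by 1.20 and THBS1, the matrix glycoprotein thrombospondin 1, by 1.12, although 2 of the 5 kept THBS1 probe sets had the opposite sign.

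**Figure D2:**
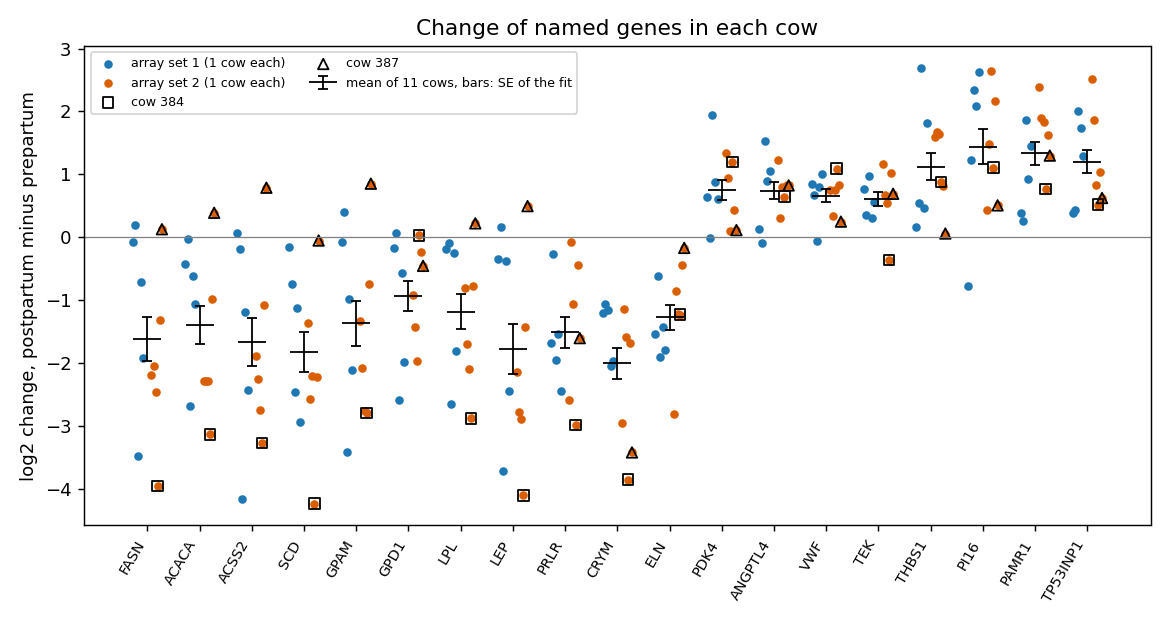
Change in log2 expression, postpartum minus prepartum, of 19 named genes in each of 11 cows (vertical axis, log2 units; blue, array set 1; orange, array set 2; open square, cow 384; open triangle, cow 387), with the mean as a black line and the SE of the fit as bars. FASN averaged -1.62 and PDK4 averaged 0.74.

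All 16 kept genes of the fatty acid synthesis list had a negative change (median -0.60), and 5 fell past the threshold over all genes, against 14 adjusted over the list alone. They included ACSS2, which activates acetate, the main lipogenic carbon source of ruminants (log2 change -1.67, SE 0.38, adjusted p = 0.0288), and ACACA, which makes malonyl-CoA (-1.40, SE 0.30, adjusted p = 0.0213). Camera placed the list below the other genes (adjusted p = 2.32e-09), and adjusted p = 0.535 with an estimated correlation. Of 12 triglyceride synthesis genes, 4 fell, and 7 adjusted over the list alone; they included GPAM, which acylates glycerol phosphate (-1.37, SE 0.35, adjusted p = 0.0476), and GPD1 (-0.93, SE 0.24, adjusted p = 0.0451), neither of which passed with no filter or with an ordinary paired test. That list had a camera adjusted p = 0.00187, and adjusted p = 0.535 with an estimated correlation. DGAT2 had a change of -1.29 (SE 0.37) that did not pass (adjusted p = 0.0673, and 0.0128 without cows 384 and 387). SREBF1 (-0.44, adjusted p = 0.151), THRSP (-0.85, adjusted p = 0.224) and PPARG (-0.25, adjusted p = 0.519) did not pass, and none of the 15 kept lipogenic and adipogenic regulators did, over all genes or adjusted over the list alone (camera adjusted p = 0.68).

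**Figure D3:**
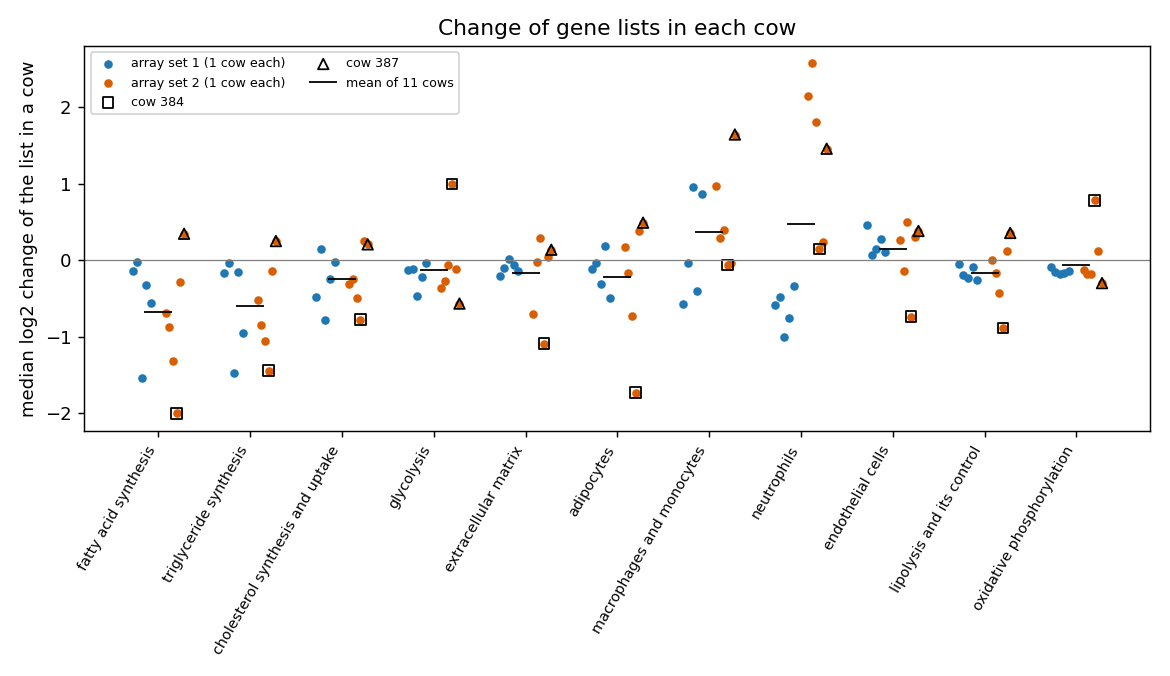
Median log2 change of each of 11 gene lists in each of 11 cows (vertical axis, log2 units; blue, array set 1; orange, array set 2; open square, cow 384; open triangle, cow 387), with the mean over cows as a black line. The fatty acid synthesis list averaged -0.67, with 10 of 11 cows below 0.

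Lipoprotein lipase LPL, which releases fatty acids for uptake, fell 2.27-fold (log2 change -1.18, SE 0.28, adjusted p = 0.0323), and ANGPTL4, its inhibitor, rose 1.67-fold (log2 change 0.74, SE 0.13, adjusted p = 0.00805). They were the 2 called genes of 16 in fatty acid uptake and the lipid droplet, where 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.36). No gene of 11 in lipolysis passed over all genes and 1 was lower adjusted over the list alone (camera adjusted p = 0.233): the lipases LIPE and PNPLA2 had changes of 0.13 (adjusted p = 0.754) and -0.20 (adjusted p = 0.512). ADRB1 and ADRB3 lay below the filter, and no probe set carried the single symbol PLIN1 or IRS1.

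Of 14 insulin signalling and glucose use genes, 2 fell and 1 rose, against 3 and 1 adjusted over the list alone (camera adjusted p = 0.46). SLC2A1, a basal glucose transporter, fell by 1.33 log2 units (SE 0.28, adjusted p = 0.0183), whereas the insulin-responsive transporter SLC2A4 had a change of -0.52 (adjusted p = 0.174) and INSR of 0.29 (adjusted p = 0.231). In glycolysis, 14 of 16 genes had a negative change. ALDOC fell by 0.55 log2 units, the single call, also adjusted over the list alone. Camera gave the glycolysis list adjusted p = 0.0296, and 0.535 with an estimated correlation. The camera adjusted p was 0.000204 to 0.159 without single cows and 0.113 without cows 330, 331, 341 and 382. In cholesterol synthesis 13 of 14 were negative and EBP fell by 0.59, again the single call, also adjusted over the list alone (camera adjusted p = 0.034, 0.745 with an estimated correlation, 0.009 to 0.122 without single cows and 0.84 without cows 330, 331, 341 and 382). ACADVL, the very long chain acyl-CoA dehydrogenase, rose by 0.66 as the 1 call, also adjusted over the list alone, of 17 fatty acid oxidation genes (camera adjusted p = 0.955). None of 42 oxidative phosphorylation genes passed, nor any adjusted over the list alone (camera adjusted p = 0.141), but camera placed that list lower without cows 384 and 387 (adjusted p = 3.45e-05, and adjusted p = 0.546 with an estimated correlation).

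PRLR, the prolactin receptor, fell 2.86-fold (log2 change -1.52, SE 0.25, adjusted p = 0.00495, 11 of 11 cows), the 1 call, also adjusted over the list alone, among 8 nuclear and hormone receptors (camera adjusted p = 0.111). GHR and IGF1 had changes of 0.30 (adjusted p = 0.445) and -0.27 (adjusted p = 0.183), and none of 14 genes of the growth hormone axis passed, over all genes or adjusted over the list alone (camera adjusted p = 0.454). ERRFI1 fell by 0.68 as the 1 call, also adjusted over the list alone, among 8 glucocorticoid targets (camera adjusted p = 0.185). LEP was the 1 call, also adjusted over the list alone, among 8 adipokines (camera adjusted p = 0.672, direction down), whose median was 0.07 while their mean was -0.24. ADIPOQ, which encodes adiponectin, had a change of 0.00 (SE 0.19, adjusted p = 0.998).

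Of 14 macrophage and monocyte markers, all had a positive change (median 0.41), but none passed on its own or adjusted over the list alone, and the list median was below 0 in 5 of 11 cows (exact sign-flip p = 0.107). Camera placed the list higher (adjusted p = 0.00225), with adjusted p = 0.745 with an estimated correlation, 0.0565 without cows 384 and 387, 0.492 in array set 1 alone (median 0.09) and 4.63e-07 in array set 2 alone (median 0.59). Among 13 endothelial markers VWF, a clotting factor carrier, rose by 0.66 and the angiopoietin receptor TEK by 0.61, both also adjusted over the list alone (camera adjusted p = 0.0269, 0.745 with an estimated correlation, 0.00015 to 0.0639 without single cows, 0.166 in array set 2 alone and 0.345 without cows 330, 331, 341 and 382). Of 15 adipocyte markers 2 fell, LEP and GPD1, and 4 adjusted over the list alone (camera adjusted p = 0.0401, 0.745 with an estimated correlation, 0.013 to 0.287 without single cows and 0.104 without cows 384 and 387). The median of the adipocyte markers was lowest, at -1.76 log2 units, in the postpartum array of cow 384, which had the highest skeletal muscle markers. Of 31 extracellular matrix genes 3 fell and THBS1 rose, against 7 and 1 adjusted over the list alone (camera adjusted p = 0.0269, 0.745 with an estimated correlation, 0.00631 to 0.183 without single cows and 0.0841 without cows 384 and 387). Without cows 330, 331, 341 and 382 the extracellular matrix and adipocyte lists had camera adjusted p = 0.101 and 0.113. ELN, which encodes elastin, fell by 1.28 (SE 0.20, adjusted p = 0.00349), and had a change of -0.94 (adjusted p = 0.128) in the 7 cows without high KRT10.

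The remaining lists were not called by camera, with adjusted p from 0.0649 (unfolded protein response) to 0.869 (brown adipocytes). MCM7, a replication helicase subunit, rose by 0.26 among 12 cell cycle genes, IER3 fell by 0.45 among 19 immediate early genes, IFI27 fell by 0.89 among 12 interferon response genes, and MFAP5 fell by 0.45 while PI16 rose among 16 fibroblast and progenitor markers, and the same genes were the calls adjusted over each list alone. No member passed over all genes among 12 tricarboxylic acid cycle, 15 unfolded protein response, 6 circadian clock, 17 inflammatory, 9 lymphocyte, 5 neutrophil, 10 smooth muscle, 17 skeletal muscle or 4 brown adipocyte genes. Adjusted over the list alone, 2 clock genes and 1 inflammatory gene were lower and 3 inflammatory genes and 1 neutrophil marker were higher. The erythrocyte and epidermis lists kept 2 genes each and were not given to camera; KRT10 was lower adjusted over the epidermis list alone. In all 8 lists were called by camera, 2 higher and 6 lower, and none with an estimated correlation. Fatty acid synthesis and triglyceride synthesis kept the call in every alternative of camera with the preset correlation, and the remaining called lists lost it in some.

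The second comparison asked whether the postpartum effect differed between the array sets. SCD averaged -1.49 in set 1 and -2.11 in set 2, FASN -1.20 and -1.97, PRLR -1.58 and -1.46, and PDK4 0.81 and 0.69. No probe set of 14410 passed limma's interaction test, and 516 had an unadjusted p under 0.05. Cows 384, 386 and 387 all belong to set 2. Within set 1 alone 69 probe sets passed, and within set 2 alone none did, with 1526 at an unadjusted p under 0.05 by the same limma test. Across probe sets, which are not independent replicates, the changes in both sets correlated at r = 0.52.

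The arrays labelled cow 387 differed at probe sets that separate cows. At 9 probe sets the other 10 cows fell into a high and a low level with both arrays of each cow on the same side, and the pair labelled 387 was split at 6 of them, among them the major histocompatibility genes BOLA-DQA5, BOLA-DQB1 and BOLA-N. BOLA itself measured 3.56 on the log2 scale in the prepartum array and 12.38 in the postpartum array. Without cow 387 alone, 621 probe sets passed limma's test of the postpartum effect.

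**Figure D4:**
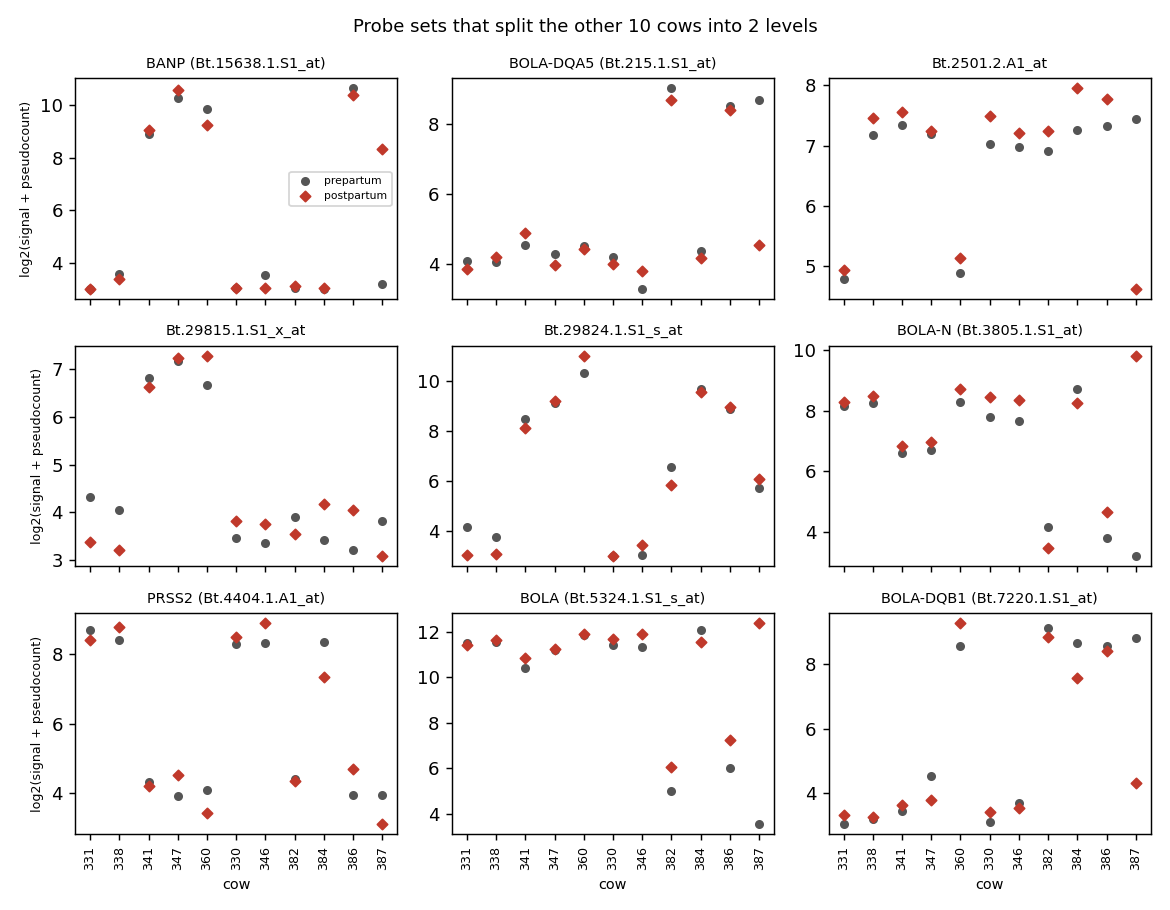
Level (vertical axis, log2 of signal plus pseudocount) of 9 probe sets that divide the other 10 cows into a high and a low level, in each array by cow, with grey circles for prepartum and red diamonds for postpartum. The pair labelled cow 387 is split at 6 of the 9.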

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

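The test between array sets and the estimated correlation within them were chosen after the values per cow had been seen. The neutrophil list kept 5 of 11 markers (S100A8, S100A9, S100A12, FCGR3A and ITGB2), and S100A8 and S100A9 are also in the inflammatory mediator list. The list median moved in opposite directions in the array sets. It was below 0 in each of 5 cows of set 1 (mean log2 change -0.63, SD 0.26, n = 5) and was above 0 in each of 6 cows of set 2 (mean 1.40, SD 1.0, n = 6). The difference was 2.03 log2 units (exact permutation p = 0.00649 over 462 divisions of the cows, and 0.201 after Benjamini-Hochberg adjustment over 31 lists, where 462 divisions are too few for a single list to pass). Camera placed the list lower in array set 1 alone (adjusted p = 0.019, and 0.47 with an estimated correlation) and higher in array set 2 alone (adjusted p = 6.87e-05, and 0.663 with an estimated correlation). In array set 2 alone camera also placed macrophage and monocyte markers higher (adjusted p = 4.63e-07, and 0.663 with an estimated correlation). Inflammatory mediators were higher there too (camera adjusted p = 0.0186, and 0.8 with an estimated correlation). Whether neutrophils as cells differed was not tested.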

How the results depend on the processing

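Leaving out 2 or more cows, the muscle covariate, fry, the sign-flip test of lists and an estimated correlation within array sets were chosen after the data were seen; the others, leaving out single cows among them, were planned. Against 494 probe sets, the postpartum effect gave 291 with an ordinary paired test, 286 with an exact signed-rank test, 1076 with array weights, 69 in array set 1 alone, 0 in array set 2 alone (1526 at an unadjusted p under 0.05), 1048 at an adjusted p under 0.10, 243 with a fold of at least 1.5, 1070 without cows 384 and 387, 950 without cows 384, 386 and 387, and 6 without cows 330, 331, 341 and 382. For the last, of 60 random sets of 4 cows left out, 12 gave 6 calls or fewer (median 98), all 12 among the 19 sets that kept cows 384 and 387 (median 1). Leaving out single cows gave 242 to 969: 263 without 341, 314 without 347, 265 without 360, 280 without 330, 247 without 346, 242 without 382 and 969 without 384. Without the replicate block 338 passed, with cow as a random effect 708, and with the muscle covariate 654, each within 1.5 times.

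Against 8 lists, camera called 5 with no replicate block, 5 with the 60th percentile filter, 10 with no filter, 11 in array set 1 alone (1 higher), 6 in array set 2 alone (3 higher), 0 with an estimated inter-gene correlation (also in each array set alone), 4 without cows 330, 331, 341 and 382, and 5 to 8 without single cows. Fry called 0 lists over 11 cows, as did the exact sign-flip test of list medians. Without cows 384 and 387, 6 lists had a fry adjusted p = 0.0399. Camera had called fatty acid synthesis, glycolysis and endothelial cells among them over 11 cows. It had not called insulin signalling and glucose use, oxidative phosphorylation, or nuclear and hormone receptors. Triglyceride synthesis had a fry adjusted p = 0.069. In the sign-flip test fatty acid synthesis and triglyceride synthesis each had p = 0.00879. Unfolded protein response, not called by camera, had p = 0.0107 there. All 3 had a sign-flip adjusted p = 0.111. The cause of these differences was not tested. The difference between array sets gave 0 calls in every alternative run.

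Of 888 alternatives of the 37 called named genes, 655 kept direction and call, 233 kept direction only and 0 turned. These genes were named because they passed in the same arrays, so a turn was unlikely beforehand. The fit without a block and the ordinary paired test leave the size of the change as it was. The count of 0 is therefore weak evidence on direction. With the ordinary paired test FASN, LEP, PDK4, ACSS2, ACACA, LPL and SLC2A1 were among the genes that kept direction only. Of 264 alternatives of 11 others, 251 were the same and 5 passed (DGAT2, INSR and SLC2A4). The named gene ADIPOQ, near 0, turned to -0.0091 with median-centred arrays, -0.014 in array set 2 alone and -0.073 without cows 330, 331, 341 and 382, and ran from -0.11 to 0.15 without single cows; the cause was not tested. With 4 times the pseudocount named gene PMEL rose by 1.07, named gene ASGR1 by 1.08, named gene PI16 by 1.35 and named gene TTR by 1.27.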

Other observations

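The tests of the array labelled cow 387, of muscle and of skin, the leaving out of cows 384 and 387, and the relations without those cows were chosen after the results were seen; the sign assignments and divisions of cows, the oestrogen list and the relations over 11 cows were set before their results.

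S100G, a vitamin D dependent calcium binding protein chosen after its values were seen, fell 3.08-fold postpartum (log2 change -1.62, SE 0.33, adjusted p = 0.0165, 11 of 11 cows). KERA, SFRP2 and OLFML3, also chosen afterwards, encode proteins of the extracellular space and fell by 1.52, 1.64 and 1.53 log2 units.

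Chance assignment of the times within cows is argued against for the count of probe sets and not for the count of lists. Only 100 assignments were tried, the real one among them, so no share below 1 of 100 could be reached. Of 100 assignments of the sign within cows, 1, the real one, gave as many as 494 probe sets, and the highest other count was 285, from the assignment that turned cow 387 alone. Without cows 384 and 387, 1 of 100 gave as many as 1070, and the highest other count was 1. For gene lists 37 of 100 assignments gave 8 or more, and the highest other count was 15, so the number of lists called by camera with the preset correlation does not separate the real assignment from others. For the difference between array sets the real count was 0, which all 100 of 100 divisions of the cows must reach, so they decide nothing; the highest other count was 3.

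The arrays labelled cow 387 were split at 66.7% of 9 probe sets on which the arrays of each other cow agreed, with levels at least 1.5 log2 units apart, and at 6 of 13 or 4 of 6 with levels 1 or 2 apart. In the other cows, tested with cow 387 left out of the rule after a first version left 3 probe sets each, at most 1 of 6 to 10 probe sets was split. Muscle RNA is argued against as the source, because of 7 probe sets split in cow 387, among 10 chosen without cows 384 and 387, 14.3% were split in cow 384, and an exchange with cow 384 because the prepartum array labelled 387 matched that cow at 55.6%. It matched cow 382 at all 9 and cow 386 at 88.9%, whereas the postpartum array matched no cow above 77.8% (341, 347 and 360) and cow 382 at 33.3%. A mislabelled array could give these values. Which of the 2 arrays it would be and which animal it came from stay open, since several of the probe sets belong to the linked histocompatibility region. No biological explanation other than muscle RNA was tested.

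Skeletal muscle transcripts may come from muscle tissue in the biopsies. In both the postpartum array of cow 384 and the prepartum array labelled cow 387, 13 of 17 markers stood over 2 log2 units above the median of the other arrays. These arrays were picked by the median of the same markers, so the count restates that and cannot decide where the transcripts came from. CKM, MYH7, MYL11 and TPM1 did not stand that far above, at the probe sets used. A response to lactation is argued against, since the list median rose by over 1 log2 unit in 1 of the other 9 cows (cow 386). The difference of -7.56 in the pair labelled 387 decides nothing, because its 2 arrays may not come from the same animal.

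Epidermal transcripts in 4 prepartum arrays may come from skin in the biopsies, although 1 of 2 kept KRT5 probe sets was not raised there. KRT14, below the filter, reached 5.92, 11.33, 6.12 and 9.68 in cows 331, 341, 330 and 382 and at most 5.48 in the other arrays. One DSG1 probe set, also below the filter, reached 5.78, 10.04, 4.88 and 8.26, against at most 4.73. The signal was broader in cows 341 and 382. KRT17 reached 7.89 and 6.45 and SFN 6.57 and 5.54 there. In cows 331 and 330 KRT17 (3.56 and 3.54) and SFN (4.02 and 4.18) were within the range of the other arrays (up to 4.21 and 4.75). The test of skin took the 286 lower probe sets with the lowest limma p in those 4 cows alone (median change -0.85). Of these, 153 were also called lower over 11 cows. Their median change was below 0 in each of the 7 other cows (mean -0.53, SD 0.41, n = 7, exact sign-flip p = 0.0156). That p is the smallest that 7 cows can give. The 7 include cow 384 (-1.36), whose postpartum array was rich in muscle markers, and the pair labelled cow 387 (-0.14). Cows 338, 347, 360, 346 and 386 had -0.20, -0.41, -0.60, -0.66 and -0.35. Without cows 384 and 387 too few remain for an exact sign-flip p under 0.05. For these probe sets, the values argue against skin in the 4 arrays as the whole cause, but the test passes only with those cows. KRT10 itself had a change of -0.32 (SE 0.18, adjusted p = 0.561) in the 7 cows, so some skin there is not excluded. ELN, KERA, SFRP2 and OLFML3 kept a negative change in the 7 cows (-0.94, -1.36, -1.40 and -1.41) but none passed. A smaller contribution of skin to single genes stays open.

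As a hypothesis, the falls of PRLR and S100G could follow the withdrawal of oestrogen after calving. A list of 20 oestrogen-induced genes that left out both kept 5 (C3, CTSD, NHERF1, EFEMP1 and CCND1), with a median change of -0.02 and a camera p = 0.808 in the upward direction. The bound set beforehand, a p of 0.05 or more, was met, but 5 genes on both sides of 0 exclude nothing, and the hypothesis stays open.

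A further hypothesis was that cows with a larger fall of fatty acid synthesis genes would gain more macrophage or endothelial transcripts, tested as 2 relations over 11 cows. For macrophages Pearson's r was 0.04 (permutation p = 0.895, adjusted 0.895) and Spearman's rho -0.07 (permutation p = 0.84, adjusted 0.84), with r = 0.07 without the 2 cows farthest from the median (384 and 341), -0.77 within array set 1 (n = 5) and 0.68 within array set 2 (n = 6). For endothelial cells r was 0.59 (permutation p = 0.0504, adjusted 0.101) and rho 0.38 (permutation p = 0.246, adjusted 0.491), with r = 0.08 without those cows, 0.27 within array set 1 and 0.67 within array set 2. Without cows 384 and 387 the macrophage relation had r = -0.68 (exact permutation p = 0.0485, adjusted 0.0971, n = 9) and rho = -0.73 (exact permutation p = 0.0311, adjusted 0.0622), with r = -0.69 without the 2 cows then farthest from the median, and the endothelial relation had r = 0.02 (exact permutation p = 0.959) and rho = 0.03 (exact permutation p = 0.948), with r = 0.53 without the same 2 cows (341 and 382). The endothelial r and rho over 11 cows had the sign opposite to the hypothesis. No relation passed after adjustment, both depend on the cows in doubt, and the number of cows is too small to exclude either.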
